A study of Mus musculus with 18 samples.

How the data were processed

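Gene expression was measured on Affymetrix Mouse Gene ST arrays in isolated pancreatic islets of 2 obese mouse models and their lean controls. The labels describe C57BL/KsJ db/db mice as prone to diabetes and C57BL/6J ob/ob mice as resistant to it, each sampled at 6 and 16 weeks with age-matched lean controls. Both obesity mutations act on the leptin pathway: ob/ob mice lack the hormone and db/db mice lack its long receptor form. The larger value table held 16 arrays in 8 groups of 2. A smaller table held 2 further arrays from a related array design, 1 lean and 1 db/db KsJ array of 16 weeks, numbered replicate 3 below.

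The deposited values were log2 signals per transcript cluster, and the submitters' processing notes name MAS5, RMA and Partek without versions or roles. The background correction and the order of the steps are not given in the sources used here. The 2 tables came from different array designs and had different distributions. The sources used here do not say whether they were normalized together. The tests therefore stayed within the larger table, except for 1 alternative that joined both with the table as a block. Each table held 41034 clusters. The platform annotation gave 1 gene for 23521 of them, several for 1814 and no row for 15699, and symbols were updated through Entrez IDs for 23328 clusters with the GRCm38.p6 gene table. Clusters with several genes or no row were not used. Of the planned list members, 46 had no cluster of their own and were not analysed here, 13 of them named only in rows of several genes and 33, Ins1 among them, in no row.

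Where a gene had several clusters, the cluster with the highest mean was kept, which gave 22180 genes. Genes below the 30th percentile of the mean, a log2 value of 2.99, were left out, and 15526 genes were tested. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 16 arrays, with 8 residual degrees of freedom shared by all groups, and moderated the variances with eBayes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The labels do not say whether the 2 arrays of a group came from separate animals or from pools. P-values therefore measure only the spread between these samples, and the number of arrays limits the precision.

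Gene lists, 28 in all, covered endocrine and other cell types, stress responses, metabolism, proliferation and inflammation. They were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 28 lists within a comparison. camera compares a list with all other genes, whereas fry tests whether the list's own genes move, on balance, one way. Members past the threshold were counted over all genes tested and adjusted over the list alone. The comparisons, lists, settings and the rule for named genes were fixed before the data were examined. The rule named, among called genes whose obese arrays all lay beyond the lean arrays, up to 5 with the most positive and 5 with the most negative change, without predicted genes, up to 4 members per list with the smallest p, and a fixed set of islet and control genes. The comparisons of lean groups named up to 3 genes each way.

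On simulated values with the real genes' variances, 28.4% of log2 changes of 1, 74.2% of changes of 1.5, 88.2% of changes of 2 and 98.0% of changes of 3 were called for 16-week db/db against lean islets, over 15526 genes. Of the simulated calls, 4.50% were false. The simulated noise was independent between genes and had the same variance in all groups, unlike the real arrays. These rates therefore do not give the error or detection rates of the real comparisons. Alternatives fixed at the same time were other filters on dim genes, quantile normalization, median centring, other variance models, array weights, the mean over clusters, a minimum log2 change of 1, the compared groups alone, both tables joined with the table as a block, and each array left out in turn. Alternatives chosen after seeing the data left out arrays with low correlations or an unexpected profile, normalized only the tested genes, added the acinar and an enterocyte list as covariates, added a term for the level of Xist with all arrays or without lean KsJ 16-week replicate 2, or left out arrays outside the compared groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.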

Results

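Expression was compared in islets of diabetes-prone db/db mice on the KsJ background, diabetes-resistant ob/ob mice on the 6J background and lean mice of both strains, at 6 and 16 weeks, with 2 arrays per group and 41034 transcript clusters per array. Array medians in the larger table lay between 3.51 and 3.83 on the log2 scale. The correlation between the arrays of a group, taken across clusters, was lowest in lean KsJ islets of 16 weeks (0.916) and lean 6J islets of 6 weeks (0.960), and highest in lean 6J islets of 16 weeks (0.980). In the larger table the sample titles carry 1 code on all KsJ arrays and another on all 6J arrays, so strain cannot be told apart from whatever these codes mark.

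Markers of other tissues differed between arrays of a group. The acinar cell list, genes of digestive enzymes, averaged 12.06 on lean KsJ 16-week replicate 2 against 9.25 on replicate 1, with the chymotrypsin gene Ctrc at 13.20 against 9.53. An enterocyte list written after the values were seen averaged 10.92 on lean 6J 6-week replicate 2 against 3.80 on replicate 1. It averaged 9.30 and 6.25 on db/db 16-week replicates 2 and 1, and the sucrase-isomaltase gene Sis, chosen after its values were seen, stood at 10.94 and 9.03 on the 2 highest of these arrays. In 6-week ob/ob islets the dedifferentiation list averaged 7.34 on replicate 1 and 5.86 on replicate 2, against 5.82 and 5.98 in lean islets. The Y-linked gene Uty, chosen after its values were seen, was at 7.25 to 7.86 on 5 arrays, and at 2.17 to 3.60 on the others. The 5 were replicate 1 of both lean KsJ groups and of lean 6J at 6 weeks and both ob/ob arrays of 6 weeks. Xist, expressed from the inactive X chromosome and chosen likewise, ran the other way, at 3.24 and 8.90 in lean KsJ islets of 16 weeks. The labels give no sex, but arrays of both sexes were present. No db/db array had a high Uty value, 3 lean groups held 1 array with it and 1 without, and ob/ob arrays had it at 6 weeks and not at 16. Sex was therefore not balanced in the db/db comparisons, in the 6-week ob/ob comparison or between ages in lean 6J islets. Nor was it balanced between lean strains at 16 weeks, in the differences between models or in the age change of the ob/ob effect. It was balanced between 16-week ob/ob and lean 6J islets, where no array had a high Uty value, and between ages in lean KsJ islets. Between lean strains at 6 weeks it was also balanced.

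**Figure D1:**
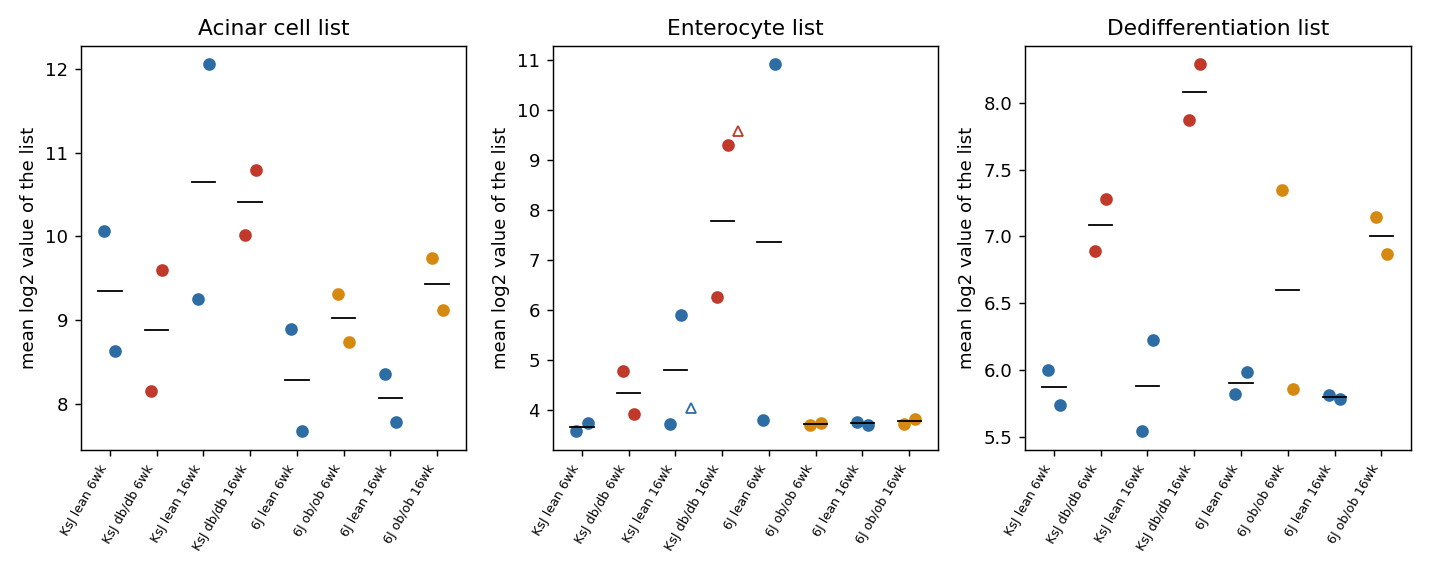
Mean log2 value of 3 gene lists on each array, by group, with filled circles for arrays of the larger table, black bars for group means and, in the enterocyte panel, open triangles for the smaller table. Lean KsJ 16-week replicate 2 had the highest acinar mean, 12.06, and lean 6J 6-week replicate 2 the highest enterocyte mean, 10.92.

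At 16 weeks, db/db islets, which carry the diabetes-prone genotype, had far more of several transcripts than lean KsJ islets, some of them markers of dedifferentiated or immature endocrine cells. Aldh1a3, a retinaldehyde dehydrogenase used as a marker of failing beta cells, rose by 6.22 ± 1.13 on the log2 scale (SE; n = 2 arrays per group; adjusted p = 0.0197, limma). The gut hormone genes Cck (5.42 ± 1.01) and Gast (3.18 ± 0.56), the thyroxine-binding globulin gene Serpina7 (5.29 ± 0.93) and the guanylin receptor gene Gucy2c (4.39 ± 0.61) also rose. The kappa-casein gene Csn3 was at 6.40 on average, against 2.58 in lean islets, below the cutoff of 2.99 for dim genes, so no fold is given. Intestinal markers were higher on the same arrays, with enterocyte means of 6.25 and 9.30 against 3.71 and 5.89 and goblet cell means of 5.86 and 5.96 against 3.95 and 4.26 in lean islets. On the enterocyte-rich lean 6J array Cck (6.68 against 4.38 on its partner) and Gucy2c (9.73 against 8.80) were higher too. With the acinar and enterocyte means as covariates Cck stood at 4.76, Gast at 2.99 and Gucy2c at 4.22, all called. Such kept calls do not exclude an intestinal source, since these means need not track the cells that express the 3 genes. These genes were not high in db/db islets alone. On the 16-week ob/ob arrays Gucy2c was at 10.51 and 10.52, against 7.81 and 7.78 in lean 6J islets. Cck was at 7.14 and 6.29 against 4.24 and 4.06, and Gast at 6.24 and 5.61 against 5.39 and 5.22. Enterocyte means on these ob/ob arrays were 3.72 and 3.83. In db/db against lean islets other genes went down. Among the genes that fell were Cox6a2, a cytochrome oxidase subunit, by 3.05, Car15, Chrna4, Frat1 and Tdrd6. The beta-cell transcription factor gene Mafa fell by 1.26 (adjusted p = 0.0473). Ins2 (0.24 ± 0.16), Gcg (0.09 ± 0.14), Sst (0.12 ± 0.15), Ucn3 (-0.26 ± 0.25), Hspa5 (0.19 ± 0.25), Mki67 (0.30 ± 0.47) and the glucose transporter gene Slc2a2 (-1.05 ± 0.38) did not pass the test. Under median centring Gcg, Sst and Hspa5 had the other sign, as did Hspa5 (-0.13) and Mki67 (-0.29) without lean replicate 2, Hspa5 (-0.10) without db/db replicate 1 and Ucn3 (0.06) without lean replicate 1.

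In the dedifferentiation list 7 of 11 measured genes rose, the same number when adjusted over the list alone, among them the hyaluronan receptor gene Cd44 (2.63 ± 0.39). Its median change was 2.03, with a camera adjusted p of 0.00795 at the preset correlation (adjusted p = 0.652 with an estimated correlation). Genes of extracellular matrix and stellate cells rose in 5 of 21 cases (13 adjusted over the list alone), with Col3a1 (2.83 ± 0.27), Col1a1 (2.90 ± 0.34), Postn (2.22 ± 0.28) and the pericyte gene Rgs5 (1.29 ± 0.25). The list's median change was 1.21 (adjusted p = 0.652 with an estimated correlation). Macrophage genes rose in 4 of 20 cases (13 adjusted over the list alone), namely C1qa (1.12 ± 0.18), Tyrobp (1.48 ± 0.27), Fcer1g (1.18 ± 0.27) and Cd68 (1.71 ± 0.39), with a list median of 1.20 (adjusted p = 0.652 with an estimated correlation). Of 15 endothelial genes Cdh5 (1.19 ± 0.29) and Plvap (0.92 ± 0.23) rose, 4 adjusted over the list alone (adjusted p = 0.729 with an estimated correlation). fry gave adjusted p-values of 0.00754, 0.00708, 0.00708 and 0.0402 for these 4 lists. It gave 0.00708 for the hypoxia and glycolysis list, which camera did not call (adjusted p = 0.343 at the preset correlation and 0.729 with an estimated one), where P4ha2 (1.40 ± 0.30), Egln3 (2.22 ± 0.56) and Pfkfb3 (1.41 ± 0.37) rose. fry tests against 0, and the median change of all genes was 0.18 here. It also called 9 of 28 lists between ages in lean KsJ islets and 9 between lean strains at 16 weeks. Both use the same lean KsJ 16-week arrays, so their part in the fry calls here was not separated from that of db/db.

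Secretory granule genes rose in 4 of 20 cases (11 adjusted over the list alone), with Ptprn (1.20 ± 0.26), Scg5 (1.23 ± 0.28), Chgb (1.15 ± 0.28) and Syt4 (1.49 ± 0.38). The median was 0.55 (adjusted p = 0.812 with an estimated correlation). No gene of the adaptive unfolded protein response list passed over all genes or over the list alone, although its median was 0.53 (adjusted p = 0.802 with an estimated correlation). The acinar list stood lower than other genes in camera, with a median of -0.16 and none of 25 genes called (adjusted p = 0.850 with an estimated correlation), and turned to 1.08 without the 2 arrays of lowest correlation. In the redox list Txnip (1.64 ± 0.33), Gclc (0.68 ± 0.14), Txnrd1 (0.87 ± 0.20) and the heme oxygenase gene Hmox1 (1.40 ± 0.34) rose. So did the fatty acid transporter gene Cd36 (2.90 ± 0.46), Sqle (1.16 ± 0.24), Dhcr7 (0.95 ± 0.20), Chac1 (1.29 ± 0.30) and, in the beta-cell identity list, the lipid sensor gene Gpr119 (1.49 ± 0.28). With 1 array left out the camera calls above ended, with these medians, without lean KsJ 16-week replicate 2 for secretory granule (0.18), acinar (1.08) and endothelial (0.30), without lean KsJ 16-week replicate 1 for dedifferentiation (2.01) and unfolded protein response (0.53), and without db/db 16-week replicate 1 for acinar (0.18) and unfolded protein response (0.42).

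Over all genes 900 passed the test, 826 higher and 74 lower in db/db islets, where the median change of all genes was 0.18. That median became 0.05 after quantile normalization, with 232 genes higher and 51 lower, and -0.02 after median centring, with 124 higher and 50 lower. The count was 118 without lean replicate 2, the acinar-rich array, 4687 without lean replicate 1, 103 and 43 without db/db replicates 1 and 2, and 153 without the 2 arrays of lowest correlation. Arrays outside the compared groups entered through the shared variance, with 385 genes without either lean 6J array of 16 weeks, 462 without either lean KsJ array of 6 weeks and 495 without either ob/ob array of 16 weeks. The count was also 500 without variance moderation, 6 in a fit of the compared groups alone, 0 with array weights, 592 at a log2 change of at least 1, 1517 with the acinar and enterocyte means as covariates, 1818 with a term for Xist and 2084 with both tables joined. Without lean replicate 2, in a fit that shares the db/db arrays, none of the 900 genes could change sign. For each of them both db/db arrays lay beyond both lean arrays, so the kept signs are no support. In that fit sex coincided with genotype, since the lean array left had a high Uty value (7.86) and the db/db arrays did not (2.29 and 2.61), and with a term for Xist, which rests on the other groups, it called 0 genes. Without the Xist term Gucy2c stood at 3.71 and Cox6a2 at -3.38, both called, and Aldh1a3 at 6.85 and Mafa at -1.54, which were not. Of the 45 named genes called, 5 were called without lean replicate 2, 43 without lean replicate 1, and 8 and 4 without db/db replicates 1 and 2. The beta-cell identity list had a median of -0.27 without lean replicate 2, where camera called it lower, against 0.04 with all arrays. Its adjusted p = 0.397 with an estimated correlation, and ran from 0.0622 to 0.768 over 4 fits without doubted arrays.

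The array pair of the smaller table gave the same 2 groups a separate reading, with 1 array each and hence no test. Aldh1a3 differed by 4.60, Cck by 5.17, Gucy2c by 3.95, Csn3 by 1.49, Cox6a2 by -3.11 and Mafa by -1.67 between db/db and lean islets. Other genes named above moved little or not the same way, with Chac1 at -0.06, Frat1 at -0.11, Cd68 at 0.15, Tyrobp at 0.27 and C1qa at 0.33. The matrix list had a median of 0.61, the macrophage list 0.68 and the dedifferentiation list 2.32, against 0.09 for all genes. Of the 826 genes called higher, 786 had the same sign in the pair, and of the 74 called lower 67 did. Over all genes tested 56.6% were positive. The pair was not clearly independent, since its lean array was also acinar-rich (Ctrc 13.02), its db/db array also high in enterocyte genes (Sis 9.84), and the labels do not say whether its RNA was new.

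**Figure D2:**
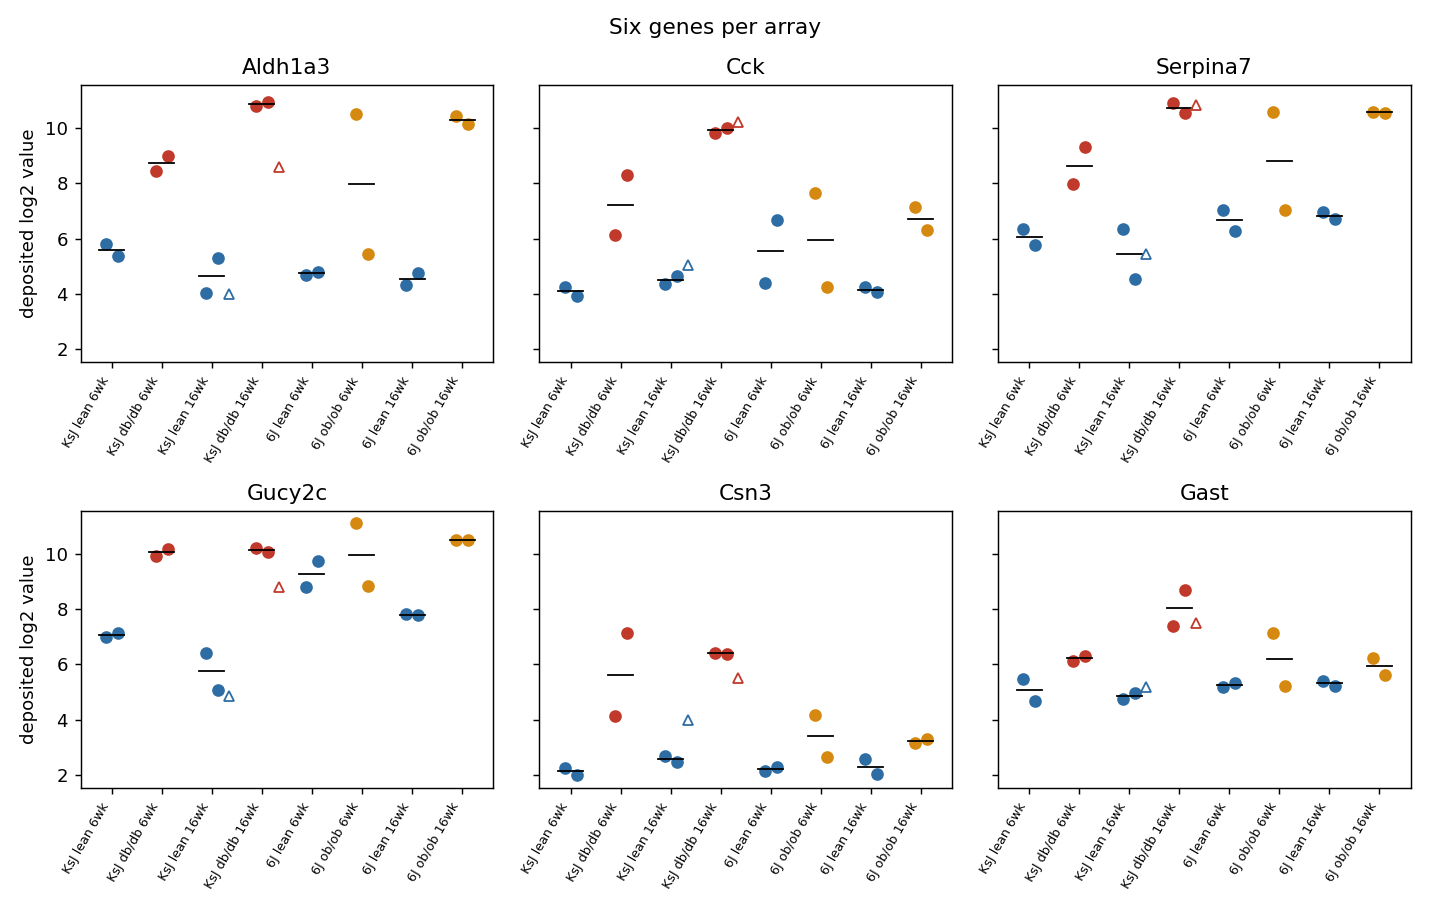
Deposited log2 values of 6 genes on each array, by group, with filled circles for arrays of the larger table, black bars for group means and open triangles for the smaller table. Aldh1a3 was at 10.79 and 10.94 in 16-week db/db islets and 4.01 and 5.29 in lean islets, and the 2 ob/ob arrays of 6 weeks lay apart at 10.52 and 5.43.

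At 6 weeks, db/db islets already differed from lean KsJ islets in a few transcripts. Kcnk9, a two-pore potassium channel gene, rose by 3.62 ± 0.32 (adjusted p = 0.00291, limma). Meltf, which encodes melanotransferrin, rose by 2.82 ± 0.32 (0.0132), and Star, which carries cholesterol into mitochondria for steroid synthesis, by 1.40 ± 0.19 (0.0416). With the predicted gene Gm5105, named here after its value was seen, these were the 4 genes called, all higher. Aldh1a3 (3.13 ± 1.13, adjusted p = 0.539), Cck (3.12 ± 1.01), and Serpina7 (2.58 ± 0.93) did not pass over all genes, and of the dedifferentiation list Cd44 alone (1.83 ± 0.39) passed when adjusted over the list alone, at 0.00714.

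Several lists shifted as wholes at 6 weeks under the preset correlation, with no member called over all genes. The unfolded protein response list had a median of 0.29 and 25 of 28 members above 0, led by Creld2 (1.35 ± 0.45), Derl3 (1.85 ± 0.67) and Sdf2l1 (0.96 ± 0.38), and 0 passed adjusted over the list alone (adjusted p = 0.543 with an estimated correlation). The cell cycle list had a median of 0.46 and 29 of 31 members above 0, with Tpx2 at 0.82 ± 0.32 and Mcm2 at 0.91 ± 0.38, and 0 passed adjusted over the list alone (adjusted p = 0.543 with an estimated correlation). The dedifferentiation list had a median of 0.95 (adjusted p = 0.513 with an estimated correlation) and the matrix list 0.30 (adjusted p = 0.573 with an estimated correlation). Lower medians were seen for the clock list, -0.52, with Ciart at -1.10 ± 0.33 and Dbp at -1.13 ± 0.44 (adjusted p = 0.513 with an estimated correlation), and for the beta-cell identity list, -0.26, with 21 of 26 members below 0 (adjusted p = 0.711 with an estimated correlation). The oxidative phosphorylation list had a median of 0.18 (adjusted p = 0.711 with an estimated correlation). fry called none of the 28 lists. Adjusted over their lists alone, the alpha-cell genes Slc7a2 (-0.84 ± 0.26) and Pou3f4 (-0.91 ± 0.29) fell and the superoxide dismutase gene Sod3 (2.24 ± 0.46) rose. The camera calls ended, with these medians, without lean KsJ 6-week replicate 1 for beta-cell identity (-0.24) and matrix (0.18), without db/db 6-week replicate 2 for beta-cell identity (-0.17) and oxidative phosphorylation (0.09), and without lean KsJ 6-week replicate 2 for oxidative phosphorylation (0.12). The oxidative phosphorylation call also ended under median centring. The count of genes was 0 without db/db replicate 2, where none of the 3 genes named first was called, 4 without db/db replicate 1, and 2 and 1 without lean replicates 1 and 2. In each of these last 3 fits 1 of the 3 was called. The count was 17 without either 6-week ob/ob array, whose spread enters the shared variance. It was 1 with the filter at the 50th percentile, 2 with trend and robust eBayes, 0 without variance moderation and 28 with array weights, 2 after median centring and 125 without all 3 doubted arrays.

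At 16 weeks, islets of the diabetes-resistant ob/ob mice held more transcript of Osgin1, an oxidative stress-induced gene (1.75 ± 0.25, adjusted p = 0.0401, limma), and of Bcat1, which transaminates branched-chain amino acids (1.56 ± 0.21, 0.0320), than lean 6J islets. The zinc finger gene Zim1 (-2.37 ± 0.31), the heparan sulfate enzyme gene Ndst4 (-2.15 ± 0.32), Hhatl (-1.99 ± 0.27), the elongation factor gene Eef1a2 (-1.97 ± 0.27) and the vasopressin receptor gene Avpr1b (-1.85 ± 0.25) fell. In all 11 genes were called, 2 higher and 9 lower, and 2570 had an unadjusted p below 0.05, against 3811 in db/db islets. The counts of calls do not rank the models, since the shared variance came from groups of unequal spread. The SD across genes of the difference between the arrays of a group ran from 0.313 in lean 6J to 0.888 in lean KsJ islets, both of 16 weeks. In fits of the compared groups alone and with array weights, more genes were called in ob/ob than in db/db islets. With the acinar and enterocyte means as covariates 0 genes were called in ob/ob islets, and the acinar list was higher there, with 25 of 25 members above 0 but 0 called (adjusted p = 0.719 with an estimated correlation). The count was 34 with the filter at the 50th percentile, 50 with trend and robust eBayes, 0 without variance moderation, 1293 in a fit of the compared groups alone and 2969 with array weights. Aldh1a3 (5.77 ± 1.13, adjusted p = 0.0691), Serpina7 (3.74 ± 0.93) and Cd44 (1.72 ± 0.39) did not pass over all genes and were the 3 of 11 dedifferentiation genes that passed when adjusted over the list alone. The list's median was 0.31 (adjusted p = 0.663 with an estimated correlation). On the 16-week arrays Aldh1a3 was at 10.43 and 10.16 in ob/ob against 4.31 and 4.76 in lean islets. Serpina7 was at 10.59 and 10.55 against 6.94 and 6.72. Their SEs rest on the variance shared by all groups. That variance includes the 6-week ob/ob arrays, at 10.52 and 5.43 for Aldh1a3 and 10.58 and 7.02 for Serpina7.

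Cell cycle genes were higher as a group in 16-week ob/ob islets. Of 31 members, 0 were called over all genes and 18 rose adjusted over the list alone, among them Tpx2 (1.66 ± 0.32), the topoisomerase gene Top2a (1.71 ± 0.35), Ccnb2 (1.92 ± 0.44) and Nusap1 (1.66 ± 0.40). The median was 1.07 (adjusted p = 0.298 with an estimated correlation; fry 0.0310). Unfolded protein response genes gave 11 of 28 adjusted over the list alone and 0 over all genes, with Derl3 (3.14 ± 0.67), Sdf2l1 (1.70 ± 0.38), the ubiquitin ligase gene Syvn1 (0.71 ± 0.17) and Ssr3 (0.96 ± 0.23), and a median of 0.61 (adjusted p = 0.298 with an estimated correlation; fry 0.0228). Genes of other endocrine cells went the other way. In the delta, PP and epsilon list 5 of 8 fell adjusted over the list alone, including Ghsr (-1.72 ± 0.28), Rbp4 (-1.56 ± 0.30) and Ppy (-0.52 ± 0.17), with a median of -0.62 (adjusted p = 0.319 with an estimated correlation; fry 0.0207). In the alpha-cell list 4 of 7 fell on the same adjustment, Irx2 (-1.69 ± 0.39), Irx1 (-1.47 ± 0.37), Pou3f4 (-1.09 ± 0.29) and Slc7a2 (-0.94 ± 0.26), with a median of -0.94 (adjusted p = 0.601 with an estimated correlation). Gcg itself was at -0.26 ± 0.14 and Sst at -0.33 ± 0.15.

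The acinar list was higher, with a median of 1.39 and 25 of 25 members above 0 but 0 called over all genes or over the list alone (adjusted p = 0.719 with an estimated correlation), and it stood beside the groups above as a marker of exocrine tissue. The beta-cell identity list was lower, at -0.35, where Trpm5 (-1.60 ± 0.39) fell adjusted over the list alone (adjusted p = 0.719 with an estimated correlation). The clock list was lower, at -0.49, with 4 of 12 lower and 1 higher adjusted over the list alone. These included Nr1d2 (-1.51 ± 0.27), Dbp (-1.90 ± 0.44), Nr1d1 (-1.57 ± 0.37) and, upward, Cry1 (0.94 ± 0.25), and the list had adjusted p = 0.609 with an estimated correlation. The oxidative phosphorylation (0.30; adjusted p = 0.719 with an estimated correlation), endothelial (0.25; adjusted p = 0.719 with an estimated correlation) and interferon (0.42; adjusted p = 0.719 with an estimated correlation) lists had positive medians. Adjusted over their lists alone, the metallothionein genes Mt1 (-1.47 ± 0.29) and Mt2 (-1.99 ± 0.41), Srebf2 (-1.16 ± 0.25) and Pdk4 (-2.34 ± 0.43) fell and Sod3 (2.62 ± 0.46) rose. The camera calls ended, with these medians, without ob/ob 16-week replicate 1 for dedifferentiation (0.30), without lean 6J 16-week replicate 1 for endothelial (0.27), without ob/ob 16-week replicate 2 for endothelial (0.26), interferon (-0.42) and clock (-0.50), and without lean 6J 16-week replicate 2 for interferon (0.32) and clock (-0.38). The count of genes was 3 without ob/ob replicate 1, 0 without ob/ob replicate 2 and 0 without either lean array of 16 weeks, and none of the 7 genes named above was then called. Through the shared variance it was 328 without either ob/ob array of 6 weeks, 311 without either lean KsJ array of 16 weeks, and 0 without a lean 6-week array of either strain or a db/db array of 16 weeks. It was 146 without the 2 arrays of lowest correlation, 1184 without 6-week ob/ob replicate 2 as well, and 0 after quantile normalization.

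**Figure D3:**
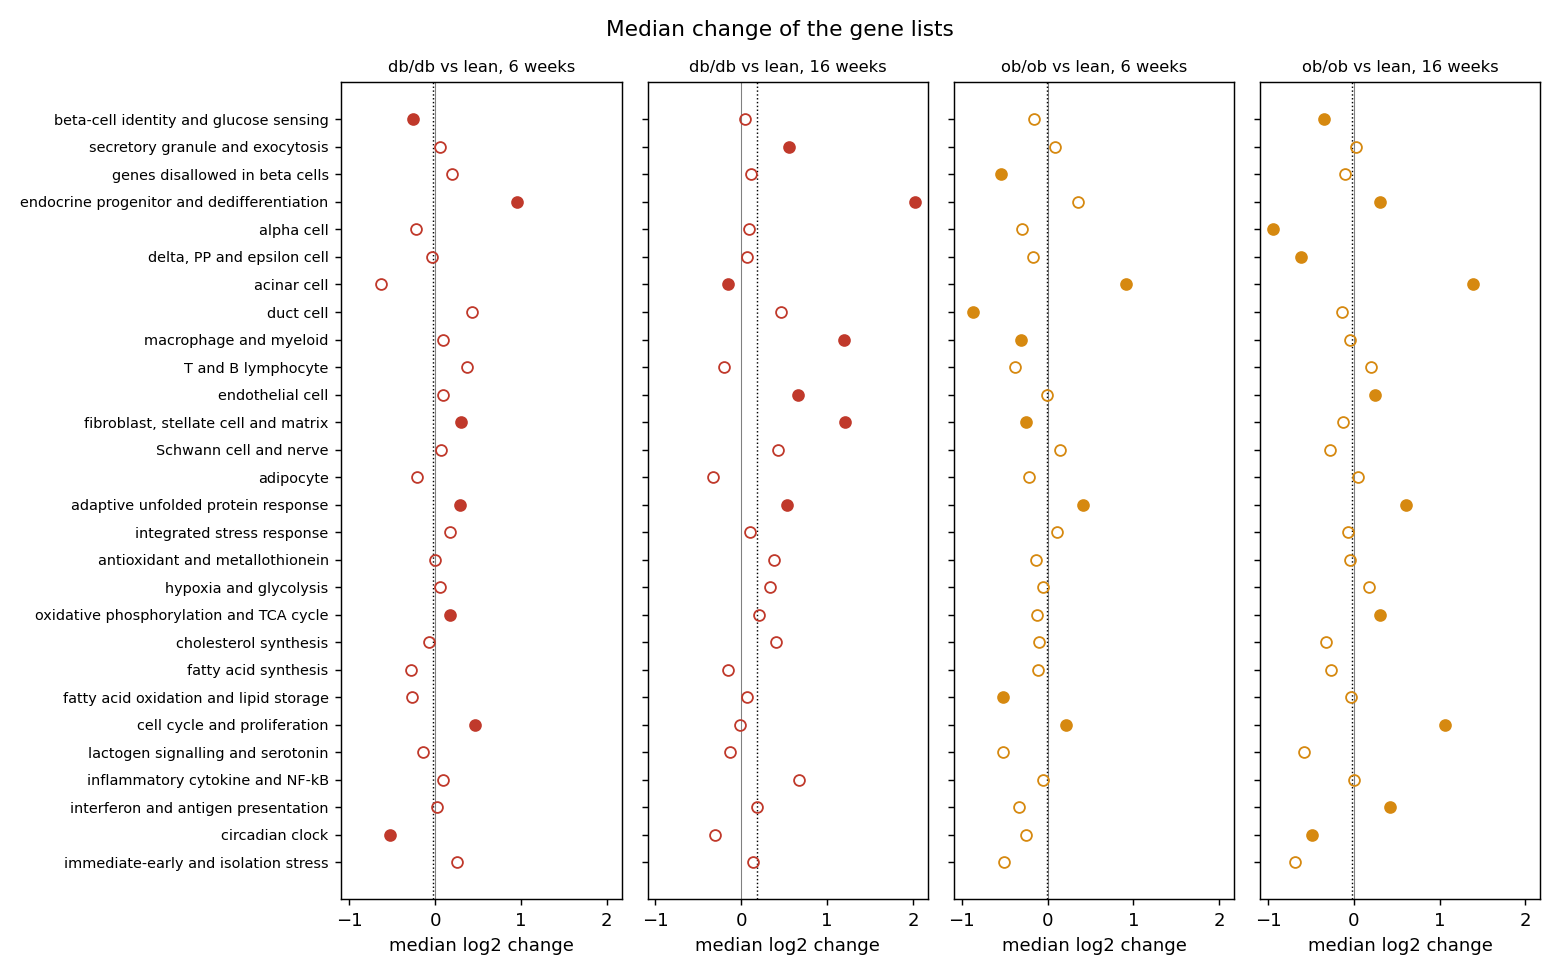
Median log2 change of each of the 28 gene lists in the 4 obese-against-lean comparisons (log2), where filled circles are lists with a camera adjusted p below 0.05 at the preset correlation, none of which passed with an estimated correlation, open circles the others and dotted lines the median of all genes. The cell cycle list had a median of 1.07 in 16-week ob/ob islets and -0.01 in 16-week db/db islets.

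At 6 weeks no gene separated ob/ob from lean 6J islets in limma, and 955 genes had an unadjusted p below 0.05. Aldh1a3 was at 3.24 ± 1.13 (adjusted p = 0.791), Serpina7 at 2.14 ± 0.93 and Slc2a2 at -0.74 ± 0.38, with replicate 1 far above and replicate 2 close to the lean arrays for Aldh1a3. The unfolded protein response list had a median of 0.41 and 26 of 28 members above 0, where Syvn1 (0.69 ± 0.17) passed adjusted over the list alone (adjusted p = 0.361 with an estimated correlation). The cell cycle list had a median of 0.21 (adjusted p = 0.689 with an estimated correlation). Lists of fatty acid oxidation (-0.52; adjusted p = 0.361 with an estimated correlation), genes disallowed in beta cells (-0.54; adjusted p = 0.689 with an estimated correlation), macrophages (-0.31; adjusted p = 0.689 with an estimated correlation), matrix (-0.25; adjusted p = 0.689 with an estimated correlation) and duct (-0.87; adjusted p = 0.689 with an estimated correlation) had negative medians. The acinar list had a positive one (0.91; adjusted p = 0.689 with an estimated correlation). Median centring moved the median of all genes from 0.00 to 0.13. Lean replicate 2 was the enterocyte-rich array. The camera calls ended, with these medians, without lean 6J 6-week replicate 2 for disallowed gene (-0.10), acinar (0.07), duct (0.03), macrophage (-0.17) and fatty acid oxidation (-0.18), without ob/ob 6-week replicate 1 for acinar (0.69) and cell cycle (0.00), without ob/ob 6-week replicate 2 for duct (-1.06), macrophage (-0.42) and matrix (-0.26), and without lean 6J 6-week replicate 1 for matrix (-0.21) and cell cycle (0.00). The count of genes was 321 without lean replicate 1, 67 without ob/ob replicate 2 and 56 without all 3 doubted arrays.

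Tested against each other, the obesity effects of both models differed at 16 weeks for 2 genes. Hunk, a kinase gene, had a db/db effect 1.87 ± 0.23 above the ob/ob effect (adjusted p = 0.0442, limma), from 1.37 in db/db and -0.50 in ob/ob islets. Sh2d5, an adaptor gene, differed by 1.77 ± 0.21 (0.0442), from 1.65 and -0.12. The cell cycle list moved apart by a median of -1.09, against 0.25 for all genes, with 5 of 31 members lower adjusted over the list alone (adjusted p = 0.523 with an estimated correlation; fry 0.0835). The matrix (1.29; adjusted p = 0.532 with an estimated correlation), macrophage (1.16; adjusted p = 0.532 with an estimated correlation) and delta, PP and epsilon (0.79; adjusted p = 0.532 with an estimated correlation) lists moved toward db/db, each with a fry adjusted p of 0.0453. Adjusted over the list alone 7 of 21, 8 of 20 and 2 of 8 members were higher. The acinar list differed by -1.55 (adjusted p = 0.532 with an estimated correlation). At 6 weeks the 2 effects differed for 0 genes in limma, with 349 at an unadjusted p below 0.05, and for 190 without lean 6J 6-week replicate 1. The median of all genes at 16 weeks became 0.05 after quantile normalization and 0.01 after median centring, and Hunk and Sh2d5 were lost under both. The 16-week count was 3730 and 4 without lean KsJ 16-week replicates 1 and 2, 8 without db/db replicate 2, 1 without 16-week ob/ob replicate 1 or either ob/ob array of 6 weeks, and 0 without 16-week ob/ob replicate 2, either lean 6J array of 16 weeks or any KsJ array of 6 weeks. Neither gene was called without db/db replicate 1, without 16-week ob/ob replicate 1, without the 2 arrays of lowest correlation (Hunk 1.93, Sh2d5 1.73) or without all 3 doubted arrays, and Hunk was not called without db/db replicate 2. The count was also 0 without the filter on dim genes, 16 with the filter at the 50th percentile, 9 with trend and robust eBayes, 4 without variance moderation, 0 in a fit of the compared groups alone, 0 with array weights, 0 with the acinar and enterocyte means as covariates and 0 with a term for Xist.

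Between 6 and 16 weeks the db/db effect grew for 1 gene, Sh2d5, by 1.92 ± 0.21 (adjusted p = 0.0324), from -0.27 to 1.65. The macrophage list shifted by 1.03 (adjusted p = 0.846 with an estimated correlation), the matrix list by 0.91 (adjusted p = 0.846 with an estimated correlation) and the cell cycle list by -0.42 (adjusted p = 0.846 with an estimated correlation), against 0.24 for all genes. That median became 0.06 after quantile normalization and 0.09 after median centring, and Sh2d5 was lost under both. The count was 3320 and 3 without lean 16-week replicates 1 and 2, 2 and 5 without db/db 16-week replicates 1 and 2, 3 without either ob/ob array of 6 weeks, 2 without either lean 6J array of 6 weeks, and 0 without any KsJ array of 6 weeks or any 6J array of 16 weeks. Sh2d5 was not called without db/db 16-week replicate 1. The count was also 0 without the filter on dim genes, 0 with trend and robust eBayes, 0 in a fit of the compared groups alone, 0 with array weights and 0 with the acinar and enterocyte means as covariates, 5 without the 2 arrays of lowest correlation and 4 without all 3 doubted arrays, where Sh2d5 was not among them. The ob/ob effect changed with age for 0 genes in limma, with 430 at an unadjusted p below 0.05. The cell cycle list shifted by 0.69 (adjusted p = 0.454 with an estimated correlation), and the count was 158 without lean 6-week replicate 1.

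Across the 15526 genes tested, the 16-week changes of both models, which share no array, had a Pearson correlation across genes of 0.274, and genes are not independent replicates. Both genes higher in ob/ob islets, Osgin1 and Bcat1, were also higher in db/db islets, and 2 of the 9 lower ones, Zim1 among them, were shared. The calls of both models rest on 1 shared variance per gene, so no chance expectation is given for this overlap. At 6 weeks the correlation was 0.255.

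**Figure D4:**
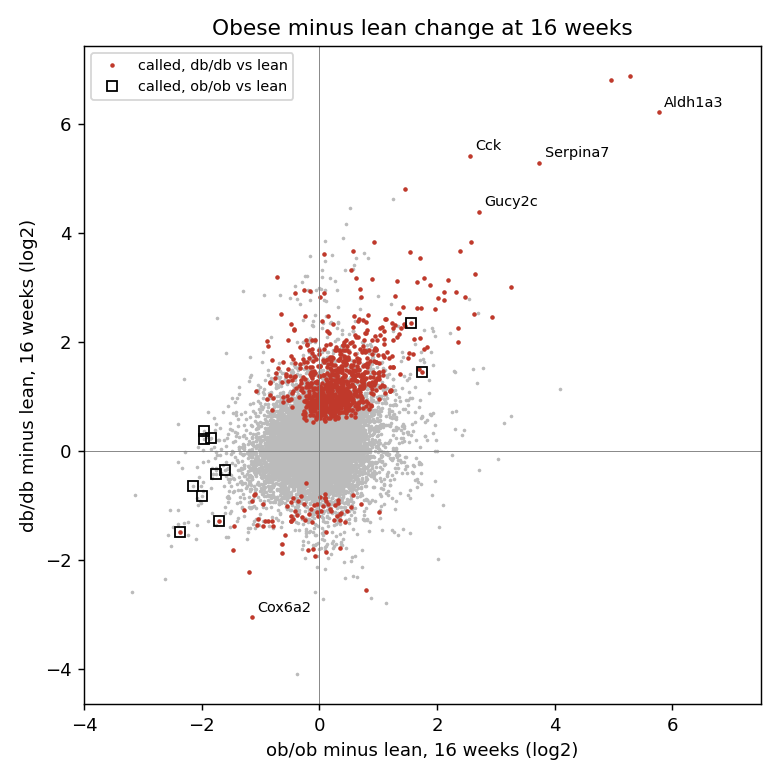
Log2 change in 16-week ob/ob islets (horizontal) against that in 16-week db/db islets (vertical), 1 point per gene tested, where red points are the 900 genes called in db/db islets and black squares the 11 called in ob/ob islets. Aldh1a3 lay at 5.77 and 6.22.

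Lean islets changed with age in no single gene, although lists moved. In 6J mice the integrated stress response list, genes induced by ATF4, was higher at 16 than at 6 weeks, with a median of 0.47 and 19 of 20 members above 0 (2 adjusted over the list alone; adjusted p = 0.0143 with an estimated correlation; fry 0.0329). Trib3 was at 1.07 ± 0.27 and Cth, the member below 0, had group means of 2.82, below the cutoff for dim genes, and 5.15, both named after their values were seen. Both lean 6J arrays of 16 weeks had a high Xist value (9.52 and 9.60). Of the 6-week arrays, replicate 1 had a high Uty value (7.54) and replicate 2 was the enterocyte-rich one. Without replicate 2 age therefore coincided with sex, and without replicate 1 with the level of intestinal markers. The integrated stress response list had medians from 0.43 to 0.54 without each of the 4 lean 6J arrays in turn. The immediate-early and isolation stress list was higher beside it, with a median of 0.80 (adjusted p = 0.755 with an estimated correlation), and lost its call without lean 6-week replicate 1 (0.68) or lean 16-week replicates 1 (0.70) or 2 (0.84). It was called in 5 of 9 alternatives. The heat shock gene Hspa1a, chosen after its values were seen, was at 10.14 and 9.95 at 16 weeks against 8.22 and 7.80 at 6 weeks. Cell cycle genes were lower, with a median of -0.53 and 9 of 31 lower adjusted over the list alone (adjusted p = 0.222 with an estimated correlation). In KsJ mice cell cycle (-0.83; adjusted p = 0.725 with an estimated correlation), endothelial (-0.87; adjusted p = 0.725 with an estimated correlation) and beta-cell identity genes (-0.60; adjusted p = 0.725 with an estimated correlation) were lower and acinar genes higher (1.37; adjusted p = 0.725 with an estimated correlation), against -0.26 for all genes, -0.09 after quantile normalization and -0.11 after median centring. Without the acinar-rich lean KsJ replicate 2 the acinar median was -0.04 and the beta-cell identity median -0.25, and neither was called. limma called 0 genes for either strain, with 4081 in KsJ and 445 in 6J islets at an unadjusted p below 0.05. The KsJ count became 5477 without lean 16-week replicate 1 and 1 without lean 16-week replicate 2, lean 6-week replicate 1 or either db/db array of 6 weeks, and the 6J count 335 without lean 6J 6-week replicate 1. The KsJ count was 7 without the filter on dim genes and 32 without variance moderation, and the 6J count 1 without variance moderation.

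Lean KsJ and 6J islets differed at 6 weeks in 40 genes, 19 higher and 21 lower in KsJ. The class II antigen gene H2-Ea (7.74 against 2.31) and Tdrd6 (5.04 against 2.19), both below the cutoff for dim genes in 6J islets, and Pianp (4.52 ± 0.44) were higher and the carbohydrate kinase gene Fggy (-3.11 ± 0.23), Tmprss2 (-2.87 ± 0.43) and Rec8 (-2.37 ± 0.41) lower. Nnt, a mitochondrial transhydrogenase gene known to be mutated in C57BL/6J mice, was 1.24 higher in KsJ islets at 6 weeks and 1.44 at 16 weeks. At 16 weeks sex was not balanced, with Uty at 7.86 and 2.49 in KsJ against 2.17 and 2.26 in 6J islets. There 639 genes differed, 73 higher and 566 lower, with a median change of -0.25 over all genes. After quantile normalization 39 were higher and 109 lower (median -0.07), and after median centring 49 and 118 (median -0.12). H2-Ea (6.80 against 2.59) and the acinar genes Ctrc (6.72 ± 1.07) and Amy2b (6.27 ± 1.47) were higher, and Fggy (-3.28 ± 0.23), Pla2g2f (-3.07 ± 0.25) and Bcl6b (-3.01 ± 0.31) lower. Ctrc did not follow the acinar gene Prss2, chosen after its values were seen, across strains. Ctrc and Prss2 were at 5.46 and 9.17 on 16-week ob/ob replicate 1 and at 8.09 and 5.74 on 6-week db/db replicate 1. The strain change of Ctrc may therefore not measure acinar content alone, and probe sequence differences between strains were not examined. The acinar list had a median of 2.37 and 19 of 25 members higher adjusted over the list alone (adjusted p = 0.461 with an estimated correlation). The 16-week count was 5805 and 83 without lean KsJ replicates 1 and 2, and 14 and 16 without lean 6J replicates 1 and 2. It was 246 without either ob/ob array of 16 weeks, 258 without either lean KsJ array of 6 weeks, 308 without either db/db array of 6 weeks and 333 without either lean 6J array of 6 weeks. The 6-week count ran from 5 without lean 6J replicate 2 to 387 without replicate 1, and was 9 and 10 without lean KsJ replicates 1 and 2 and 64 without either lean KsJ array of 16 weeks. At 16 weeks the count was also 1142 with the filter at the 50th percentile, 1084 with trend and robust eBayes, 0 in a fit of the compared groups alone, 2 with array weights, 422 at a log2 change of at least 1, 19 with the acinar and enterocyte means as covariates and 2796 with a term for Xist. At 6 weeks it was 20 without variance moderation, 1 in a fit of the compared groups alone, 94 with array weights and 10 with the acinar and enterocyte means as covariates. Without the 2 arrays of lowest correlation the counts were 93 and 17. Lep was too dim to be tested, and Lepr, at 2.78 in lean KsJ and 3.59 in db/db islets of 16 weeks, did not pass in the obese-against-lean comparisons, so neither checks the genotype labels.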

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

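All tests of explanations in this part were chosen only after the result was seen, whereas the differences between effects were planned. The obesity effects of both models differed at 16 weeks for Hunk (1.87) and Sh2d5 (1.77), and the db/db effect differed between ages for Sh2d5 (1.92), each by a test of the difference in limma. Lists are named here because camera called their difference at the preset correlation. At 6 weeks the median difference, db/db effect minus ob/ob effect, was 0.75 for the genes disallowed in beta cells list, -1.41 for the acinar cell list, 1.32 for the duct cell list, 0.48 for the macrophage and myeloid list, 0.65 for the T and B lymphocyte list, 0.68 for the matrix list, 0.24 for the oxidative phosphorylation and TCA cycle list, 0.66 for the immediate-early and isolation stress list. With 1 array left out these calls ended, with the medians given, without lean KsJ 6-week replicate 1 for acinar (-0.82), T and B lymphocyte (0.02) and immediate-early (-0.39), without db/db 6-week replicate 1 for acinar (-0.79) and T and B lymphocyte (-0.02), without lean 6J 6-week replicate 2 for duct (0.38), macrophage (0.35), T and B lymphocyte (0.16), oxidative phosphorylation (0.01) and immediate-early (0.61), without ob/ob 6-week replicate 1 for T and B lymphocyte (0.87) and immediate-early (0.55), without ob/ob 6-week replicate 2 for T and B lymphocyte (0.50) and oxidative phosphorylation (0.17), without db/db 6-week replicate 2 for oxidative phosphorylation (0.16) and immediate-early (0.07), and without lean 6J 6-week replicate 1 for immediate-early (0.76). At 16 weeks it was 0.55 for the secretory granule and exocytosis list, 0.69 for the alpha cell list, 0.79 for the delta, PP and epsilon list, -1.55 for the acinar cell list, 1.16 for the macrophage and myeloid list, 1.29 for the matrix list, -0.11 for the adaptive unfolded protein response list, 0.72 for the cholesterol synthesis list, -1.09 for the cell cycle and proliferation list, -0.41 for the interferon and antigen presentation list. These calls ended without lean KsJ 16-week replicate 2 for secretory granule (0.18) and alpha-cell (0.40), without db/db 16-week replicate 1 for secretory granule (0.53), alpha-cell (0.54) and interferon (-0.02), without ob/ob 16-week replicate 1 for alpha-cell (0.72), without lean KsJ 16-week replicate 1 for delta, PP and epsilon (0.76) and interferon (0.05), and without ob/ob 16-week replicate 2 for interferon (0.54). For the db/db effect, 16 minus 6 weeks, it was 0.55 for the secretory granule and exocytosis list, 1.03 for the macrophage and myeloid list, -0.45 for the T and B lymphocyte list, 0.91 for the matrix list, 0.56 for the cholesterol synthesis list, -0.42 for the cell cycle and proliferation list. These calls ended without db/db 6-week replicate 1 for secretory granule (0.49), T and B lymphocyte (0.55) and cholesterol synthesis (0.38), without lean KsJ 16-week replicate 2 for secretory granule (0.26) and T and B lymphocyte (-0.27), without db/db 16-week replicate 1 for secretory granule (0.51) and macrophage (0.83), without lean KsJ 16-week replicate 1 for macrophage (1.16), T and B lymphocyte (-0.77), matrix (0.76), cholesterol synthesis (0.69) and cell cycle (-0.35), without lean KsJ 6-week replicate 1 for T and B lymphocyte (0.43), without db/db 16-week replicate 2 for T and B lymphocyte (-0.70), matrix (0.41) and cholesterol synthesis (0.44), and without lean KsJ 6-week replicate 2 for matrix (0.60). For the ob/ob effect, 16 minus 6 weeks, it was 0.26 for the genes disallowed in beta cells list, -0.43 for the alpha cell list, -0.57 for the delta, PP and epsilon list, 0.33 for the acinar cell list, 0.29 for the endothelial cell list, 0.18 for the adaptive unfolded protein response list, 0.25 for the oxidative phosphorylation and TCA cycle list, 0.31 for the fatty acid oxidation and lipid storage list, 0.69 for the cell cycle and proliferation list, 0.71 for the interferon and antigen presentation list. These calls ended without lean 6J 6-week replicate 2 for disallowed gene (-0.11), oxidative phosphorylation (0.05) and fatty acid oxidation (0.12), without ob/ob 6-week replicate 1 for disallowed gene (0.24), without lean 6J 6-week replicate 1 for alpha-cell (-0.38), acinar (-0.56), endothelial (0.14) and unfolded protein response (0.07), without ob/ob 6-week replicate 2 for acinar (0.09), endothelial (0.19) and unfolded protein response (0.04), without lean 6J 16-week replicate 2 for acinar (0.02), without ob/ob 16-week replicate 1 for acinar (0.06) and fatty acid oxidation (0.36), without lean 6J 16-week replicate 1 for endothelial (0.20), and without ob/ob 16-week replicate 2 for endothelial (0.20) and interferon (-0.05). With an estimated correlation no list was called, the smallest adjusted p being 0.389, 0.523, 0.846 and 0.454 in that order. In the unfolded protein response list at 16 weeks the median of -0.11 lay below that of all genes, 0.25.

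Most genes called in 16-week db/db islets were higher, 91.8% of them. Lean KsJ replicate 2 alone is argued against as the source of that direction, since 82.2% of the 118 calls were higher without it. Sex coincides with genotype in that fit (Uty 7.86 on the lean array, 2.29 and 2.61 on the db/db arrays), and with a term for Xist it called 0 genes, with 1949 of 2330 at an unadjusted p below 0.05 higher. Differences in the arrays' distributions stay open, because the share was 82.0% after quantile normalization, 68.9% after that of the tested genes alone and 71.3% after median centring, none near an even split or near the original share. Both lean 16-week arrays had low 75th percentiles, 5.96 and 5.76 against 6.09 to 6.21 on the larger table's other arrays. At an unadjusted p below 0.05 in limma, 3632 genes were lower and 449 higher in lean KsJ islets at 16 than at 6 weeks. The direction therefore does not by itself show a broad rise in db/db islets. A term for Xist with all arrays raised the count of calls, but its basis included groups whose Xist-high array was acinar-rich or enterocyte-rich. Effects of genotype and of sex stay open and were not separated from the distributions.

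The array of 6-week ob/ob replicate 2 resembled lean arrays. Over the 2570 genes with an unadjusted p below 0.05 in 16-week ob/ob islets, the slope of its difference from the lean mean on the 16-week change was 0.119, against 0.726 for replicate 1. A swap with a lean 6-week array is argued against, because the lean arrays differed by a slope of only 0.0339 and neither carried the ob/ob profile. A single wrong label and a weakly affected animal cannot be told apart, because replicate 2 lies above the difference between the lean arrays but far below replicate 1 and there is 1 such array. Lep is too dim here to read the genotype.

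Enterocyte genes were high on lean 6J 6-week replicate 2, with Alpi at 11.97, Fabp2 at 11.68 and Apoa4 at 11.46, and on db/db 16-week replicate 2, with Alpi at 9.95 and Apoa4 at 11.12. For the lean array the design gives no biological explanation and none was tested, and for the 16-week db/db arrays a genotype effect and intestinal RNA cannot be told apart, since all carry the genotype. Enterocyte means were 6.25, 9.30 and, in the smaller table, 9.58, against 3.71, 5.89 and 4.03 in lean KsJ islets, a margin of 0.364 in the larger table, below the difference of 3.04 between its db/db arrays. For intestinal structure genes the margin of 0.78 also lay below that difference, but for goblet cell genes it was 1.60 against a difference of 0.11, so these set the groups apart. RNA of intestinal tissue may be the source on the lean array, where 16 of 18 goblet cell and intestinal structure genes, none of them in the enterocyte list, were over 1 log2 unit higher than on its partner, as 13 were on db/db replicate 2, and of which 1, Mttp, and of the 12 enterocyte genes 1, Anpep, exceeded the level of the median gene on all 16 arrays.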

How the results depend on the processing

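The alternatives that left out doubted arrays, normalized the tested genes alone, used acinar and enterocyte covariates or Xist, or left out arrays outside the compared groups were chosen only after the data were seen. Counts of called genes moved by more than 1.5 times as follows, and the cause of these moves was not tested. No filter on dim genes gave 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 7 for age in lean KsJ. A filter at the 50th percentile gave 1 for 6-week db/db, 34 for 16-week ob/ob, 16 for the 16-week difference between models, 1142 for lean strains at 16 weeks. Quantile normalization gave 283 for 16-week db/db, 0 for 16-week ob/ob, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 148 for lean strains at 16 weeks. Quantile normalization of the tested genes alone gave 2 for 6-week db/db, 151 for 16-week db/db, 0 for 16-week ob/ob, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 120 for lean strains at 16 weeks. Median centring gave 2 for 6-week db/db, 174 for 16-week db/db, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 167 for lean strains at 16 weeks. eBayes with trend and robust gave 2 for 6-week db/db, 50 for 16-week ob/ob, 9 for the 16-week difference between models, 0 for the age change of the db/db effect, 1084 for lean strains at 16 weeks. No variance moderation gave 0 for 6-week db/db, 500 for 16-week db/db, 0 for 16-week ob/ob, 4 for the 16-week difference between models, 32 for age in lean KsJ, 1 for age in lean 6J, 20 for lean strains at 6 weeks. Fits of the compared groups alone gave 6 for 16-week db/db, 1293 for 16-week ob/ob, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 1 for lean strains at 6 weeks, 0 for lean strains at 16 weeks. Array weights gave 28 for 6-week db/db, 0 for 16-week db/db, 2969 for 16-week ob/ob, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 94 for lean strains at 6 weeks, 2 for lean strains at 16 weeks. A minimum log2 change of 1 gave 592 for 16-week db/db, 422 for lean strains at 16 weeks. Leaving out lean KsJ 16-week replicate 2 and lean 6J 6-week replicate 2 gave 153 for 16-week db/db, 146 for 16-week ob/ob, 5 for the age change of the db/db effect, 1 for age in lean KsJ, 17 for lean strains at 6 weeks, 93 for lean strains at 16 weeks. Leaving out 6-week ob/ob replicate 2 as well gave 125 for 6-week db/db, 56 for 6-week ob/ob, 1184 for 16-week ob/ob, 4 for the age change of the db/db effect, 1 for age in lean KsJ, 23 for lean strains at 6 weeks, 114 for lean strains at 16 weeks. Acinar and enterocyte covariates gave 1517 for 16-week db/db, 0 for 16-week ob/ob, 0 for the 16-week difference between models, 0 for the age change of the db/db effect, 10 for lean strains at 6 weeks, 19 for lean strains at 16 weeks. A term for Xist gave 1818 for 16-week db/db, 0 for the 16-week difference between models, 2796 for lean strains at 16 weeks. A term for Xist without lean KsJ 16-week replicate 2 gave 0 for 16-week db/db. Both tables joined, with the table as a block, gave 2084 for 16-week db/db. The mean over clusters moved no count by that much. Leaving out each array in turn gave 0 to 17 for 6-week db/db, 43 to 4687 for 16-week db/db, 0 to 321 for 6-week ob/ob, 0 to 328 for 16-week ob/ob, 0 to 190 for the 6-week difference between models, 0 to 3730 for the 16-week difference between models, 0 to 3320 for the age change of the db/db effect, 0 to 158 for the age change of the ob/ob effect, 0 to 5477 for age in lean KsJ, 0 to 335 for age in lean 6J, 5 to 387 for lean strains at 6 weeks, 14 to 5805 for lean strains at 16 weeks. With 1 array left in a group, that array is assumed to vary like the other groups. The acinar list in 16-week db/db islets turned from a median of -0.16 to 1.08 (camera adjusted p = 0.0344; up to 0.405 over its alternatives) without the 2 arrays of lowest correlation, where camera called it in the opposite direction. The sign of the value turned under 1 or more alternatives for 24 of 103 list results and 16 of 151 named gene results, and 0 genes but 3 lists were called where the sign had turned. These were the acinar list above and, without lean KsJ 16-week replicate 2 and in the same camera direction, the disallowed gene list between lean strains at 16 weeks (0.37 to -0.13) and the integrated stress response list with age in lean KsJ islets (0.12 to -0.03). Of the 103 list calls of the 12 comparisons, 98 held under quantile normalization, 95 under median centring, 91 without the filter, 22 with fry, 66 without the 2 arrays and 1 with an estimated correlation, the integrated stress response list with age in lean 6J islets. In the obese-against-lean comparisons and their differences 58 named gene results were called, a gene counting once per comparison. Of these, 35 lost their call under quantile normalization, where 1 other result gained one, and 31 under median centring. Leaving out the doubted arrays ended calls of some named genes and added calls of others. Those fits leave 1 array in some groups, so no count is given. Signal over background was not analysed here, so dim genes are limited by the filter on the mean.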

Other observations

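Gene groups that the comparisons above mention little showed changes of single members in 16-week db/db islets. The oxidative phosphorylation genes Cox5b (1.04 ± 0.22) and Fh1 (0.65 ± 0.17), the duct keratin gene Krt7 (1.12 ± 0.29), the alpha-cell gene Etv1 (1.14 ± 0.28) and Igfbp4 (1.45 ± 0.38), normally silent in beta cells, rose, and Ivd (-1.38 ± 0.27), placed in the lactogen list, fell. The T and B lymphocyte list had a median of -0.20 and no member called.

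The immediate-early and isolation stress list varied between arrays of a group, with Fos at 10.97 and 8.25 in lean KsJ islets of 16 weeks and 6.43 and 11.05 at 6 weeks. The db/db array of the smaller table correlated across clusters more with db/db replicate 2 (0.937) than with replicate 1 (0.915), and its lean array more with lean replicate 2 (0.896) than with replicate 1 (0.879). Alpi was at 7.80 on lean replicate 2 and 3.94 on the lean array of the smaller table.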
